A study of Mus musculus with 12 samples.

How the data were processed

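RNA was measured by sequencing in mouse male germ cells of 2 meiotic stages, sorted by flow cytometry from C57Bl mice whose germ cells express tdTomato. Leptotene and zygotene cells (LZ) were kept in culture for 6 days, untreated or with 0.3 mM octyl-L2HG, a cell-permeable ester of L-2-hydroxyglutarate. Pachytene and diplotene cells (PD) were kept for 48 hours, untreated or with 24 mM oxamate, an inhibitor of lactate dehydrogenase. Each of the 4 groups has 3 libraries from 3 independent experiments, made with poly-A capture and a stranded kit, per the labels' protocols.

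The authors deposited 1 table with raw read counts per gene for the 12 libraries, their normalized copies, and their own comparisons with log2 fold changes and adjusted p-values. The submitters' processing notes name bcl2fastq 2.18.0.12, cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.6.0, DESeq2 1.22.2 and build GRCm38. The order of steps, the annotation release, the strand setting of the counting and the model behind the authors' comparisons are not given in the sources used here. If counting split or dropped reads shared by near-identical genes, values of gene families such as the Y-linked multicopy genes and Fthl17 are uncertain. Values of overlapping genes are uncertain too, and so are those of antisense genes, since the strand setting is not stated. The table has 55471 genes, of which 6255 carry a question mark in place of every count and were left out. None of those is protein-coding; the other 49216 genes hold whole-number counts without exception. The 12 columns of the authors' normalized values were not used. Column names show the group of each library but not which labelled replicate it is, so libraries are called A, B and C by the code that the 4 groups share.

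A quasi-likelihood test for counts had been planned, with the authors' kind of test as an alternative. Neither was run. The question marks share the columns with the counts, the unit rules applied to this work read them as text and refuse the columns as counts, and count tests are then not allowed. The columns were therefore entered as another unit, and limma was used, which had been planned only for a table without counts. That departure came from the rule and not from the data, since the deposited values are counts.

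Counts were scaled by library size and trimmed mean of M values (TMM), written out in R 4.3.3, and analysed as log2(normalized count + 1), with a pseudocount of 1, which understates changes of low genes. limma 3.58.1 (limma-trend with robust variance moderation) fitted the means of the 4 groups over all 12 libraries, with no block. The fit held 17011 genes with a mean normalized count of at least 10 over the 12 libraries. A gene was tested in a comparison where its mean over the libraries compared was also at least 10, and in the difference of the 2 treatment changes where that held in both stages. p-values were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with 0.05 as the threshold. All adjusted p-values of genes below come from limma.

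The second part of that filter was added after first results had been seen. With the minimum over 12 libraries alone, a test on simulated data gave 54 false calls among 208 for octyl-L2HG, because genes of the other stage entered the comparison near 0. With the filter as used, the simulation of 200 changed genes gave 14 false calls among 168 for octyl-L2HG (13079 genes), 8 among 144 for oxamate (15095 genes) and 10 among 168 for the stage difference (13016 genes). Changes of 1.5-fold, 2-fold and 4-fold were recovered in 52.2%, 82.1% and 97.0% of cases for octyl-L2HG. The shares were 41.8%, 68.7% and 93.9% for oxamate, and 52.2%, 85.1% and 100% for the stage difference. The changed genes were drawn only from genes with a higher mean than the filter asks for, so these shares do not cover the lowest tested genes. For the stage difference the simulated groups were alike in all but the 200 changed genes, while most tested genes differed between the real stages. Its false calls and recovered shares therefore do not describe the real stage comparison. The test of the difference between the treatment changes was not simulated.

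Before the data were examined, 25 gene lists were written, to which the X-linked and Y-linked genes of the table were added. They cover meiotic recombination, the synaptonemal complex, markers of the germ cell stages and of other testis cells, 2-hydroxyglutarate metabolism, 2-oxoglutarate-dependent dioxygenases, energy metabolism, stress responses, the cell cycle, the piRNA pathway and chromatin. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation is given for each list that was called. Genes named in the text follow a rule of the same date. It takes the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap, with a mean normalized count of at least 100 over the 6 libraries and a gene symbol that is not a clone or pseudogene name. It adds up to 4 members with the smallest p of each list that was called or had called members, and Ldha, Ldhb, Ldhc and D2hgdh whatever their p. Some genes that the rule names are not reported here. Ldhb was under the filter and has no value. Genes named outside that rule are marked as chosen after their values were seen.

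The relation between the treatment changes was computed across genes and tested by permuting treatment labels within stages over 100 splits. Relations with the stage difference share untreated libraries, so libraries without a treatment change were simulated 100 times. One form had no stage difference and another had the measured stage difference. The plan asked for unchanged groups and did not state the stage difference. Transcript length and GC content came from GENCODE M21, which is on GRCm38, for 16983 of the genes in the fit. The alternatives were other scalings, filters, pseudocounts and thresholds, a fit of only the groups compared, the shared code as a block, each library left out in turn, and other list tests. Added after seeing the data were the authors' deposited comparison, limma with voom weights, a correction for length and GC content, and the filter over 12 libraries.

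Total counts ranged from 10532504 to 21275486 per library. Log2 values of libraries of a group correlated at 0.985 to 0.991, and the 12 pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom 4.49 to 20.0), so none of these pairs was a duplicate. After group means were removed, PD libraries with the same code correlated at 0.357, 0.229 and 0.292, each above its correlation with any library of the other group and code. LZ libraries with the same code correlated at 0.0482, 0.145 and 0.0646, where A was below its highest correlation with another code, 0.0628. In the main test neither stage was treated as paired, so for PD cells it leaves out a pairing that these correlations show. The block is therefore an alternative for both, given with the processing results.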

Results

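The data are read counts per gene from 12 libraries of cultured mouse meiotic germ cells in 4 groups of 3. The groups are untreated LZ cells, LZ cells with octyl-L2HG, untreated PD cells and PD cells with oxamate. The series text says that oxamate brings 2-hydroxyglutarate (2HG) of PD cells down to the LZ level, so one treatment adds the metabolite at the early stage and the other lowers it at the later stage. Total counts were 10532504 to 15903788 in untreated LZ libraries and 11271410 to 18432143 with octyl-L2HG. They were 15202579 to 21275486 in untreated PD libraries and 19107780 to 21115131 with oxamate. Values are mean normalized counts ± SD with n = 3 per group, log2 fold changes are on the log2(normalized count + 1) scale, and SE is the standard error of the log2 fold change.

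The stage comparison asks how PD cells differ from LZ cells without treatment. Of 37 tested round spermatid markers 37 were higher in PD cells, among them Acrv1, an acrosomal protein, and Akap3, a scaffold of the sperm tail. Acrv1 stood at 1184 ± 200.2 against 0 in all untreated LZ libraries, at least 1114-fold higher against a floor of 3 counts over the group. Of 41 pachytene and diplotene markers 37 were higher and 1 was lower, with Ybx3, a germ cell RNA-binding protein, at 54882 ± 1443 against 612 ± 94.5 and Meig1, needed for spermiogenesis, 86.7-fold higher. The lists had camera adjusted p-values of 5.53e-07 and 3.48e-06, and an adjusted p = 0.328 each with an estimated correlation. The rule for naming a gene by its change asks for a mean normalized count of at least 100 and groups that do not overlap, and leaves out Gm and clone names. The 8 largest rises that met it were Slco6c1, March10, Tmbim7, Pabpc2, Prdx6b, Cetn1, Fbxw10 and Adam3, with log2 fold changes of 11.35 to 11.90. Adam3, a sperm surface protein, reached 29578 ± 166 from 10.5 ± 2.42.

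Enzymes that make and use lactate and 2HG differed between the stages. Ldhc, the germ cell lactate dehydrogenase (chromosome 7, 46861203 to 46878142 in GRCm38), rose 341-fold, from 199 ± 45.3 to 67229 ± 2946 (log2 fold change 8.41, SE 0.33, adjusted p = 1.02e-09). Ldha, the other lactate dehydrogenase subunit measured (chromosome 7, 46841475 to 46855627), rose 211-fold, from 114 ± 13.5 to 24111 ± 912 (adjusted p = 9.68e-13). D2hgdh, which acts on D-2HG (chromosome 1, 93824909 to 93852348), was higher at 58.6 ± 4.70 against 13.6 ± 5.66. The whole list of lactate dehydrogenase and 2HG genes went both ways, with 12 of 26 higher and 10 lower, and was not called (camera adjusted p = 0.754). Mdh1b, related to malate dehydrogenase, rose 341-fold, while Glud1, glutamate dehydrogenase, was 40.3-fold lower and the X-linked Idh3g 38.2-fold lower. Glycolysis genes were called higher, 21 of 28 up and 6 down, led by Slc2a3, a glucose transporter, at 54099 ± 828 against 369 ± 80.4, with Pfkp, Pfkm and Aldoa also higher. The list had a camera adjusted p of 0.0216, and an adjusted p = 0.436 with an estimated correlation.

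Genes of early meiosis were lower in PD cells. Of 27 markers of meiotic entry, leptotene and zygotene 20 were lower and 4 higher, with a median log2 fold change of -3.07 (camera adjusted p = 0.00017, and adjusted p = 0.0458 with an estimated correlation). Dmc1, the meiotic strand-exchange protein, fell 230.5-fold, from 4074 ± 315 to 16.8 ± 2.73, and Meiob, which binds single-stranded DNA at breaks, 36.5-fold. Mael, a piRNA pathway protein in the same list, went the other way and was 5.81-fold higher. The list of meiotic breaks and recombination had 22 of 33 genes lower and 8 higher, including lower Tex11 and Zcwpw1. Of 33 homologous recombination and sex-body silencing factors 18 were lower and 6 higher, among the former Topbp1, Atm, Brip1 and Scml2. The recombination list had a camera adjusted p of 0.00533 and an adjusted p = 0.328 with an estimated correlation, and the repair and silencing list 0.00874 and an adjusted p = 0.329 with an estimated correlation. Synaptonemal complex genes went both ways, 11 of 21 lower and 6 higher, and were not called (camera adjusted p = 0.114). Tex12 and Hormad2 were lower and Syce1 and Ccdc155 higher.

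Of 601 tested X-linked genes 454 were lower and 123 higher in PD cells. As a list they were called lower (camera adjusted p = 4.42e-14), with an adjusted p = 0.14 with an estimated correlation. They had a median log2 fold change of -4.56 against 0.57 for autosomal genes. The X chromosome took 3.43 ± 0.201% of counts in untreated LZ cells and 0.227 ± 0.0243% in untreated PD cells. Scml2, a Polycomb-related protein of germ cells (X, 161082525 to 161258213), fell from 18006 ± 1701 to 133 ± 7.92, and Hcfc1, Taf7l and Gm364 fell 62.1-fold, 57.8-fold and 318-fold. The 8 largest falls that met the naming rule held 5 X-linked genes, Atp6ap1, Bex2, Aifm1, Ccnb3 and Pnma5, beside Prss50, Cpne3 and Furin. Bex2 was 683 ± 113 in LZ cells and 0 in every untreated PD library, at least 649.6-fold lower against the floor of 3 counts. With the 102 X-linked genes that were at 0 in a group set to their bounds, the median was -4.53. Of 32 Y-linked genes 20 were higher and 12 lower. Ddx3y, Kdm5d and Gm47283 were 181-fold, 87.8-fold and 35.9-fold lower, and Gm21882 was at 0 in untreated LZ cells and 518 ± 40.7 in PD cells, at least 488-fold higher.

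Stress and chromatin lists had more lower than higher members in PD cells. Of 26 genes of the unfolded protein and heat shock response 20 were lower and 3 higher, with Hspa5, the main chaperone of the endoplasmic reticulum, at 11788 ± 243 against 106582 ± 10001, and Pdia4, Hspd1 and Hspa8 also lower. Of 23 p53 targets and apoptosis genes 18 were lower and 2 higher, with Apaf1, the apoptosome scaffold, 107.6-fold lower, Ccng1 and Ei24 lower, and Gadd45a at 0 in PD cells, at least 368-fold lower. ATF4 targets had 21 of 28 lower and 4 higher, with Atf4, Slc7a3 and Slc7a5 lower and Aars higher. Among 2-oxoglutarate-dependent dioxygenases, enzymes that 2HG can inhibit, 33 of 51 were lower and 13 higher, with Kdm6a, an X-linked H3K27 demethylase, 209.5-fold lower and Fto, an RNA demethylase, 16.3-fold higher, as Kdm4d and Egln2 were. Histone and arginine methyltransferases had 20 of 25 lower and 5 higher, with Kmt2a, Nsd1 and Suv39h1 lower and Setd1b higher. Of 9 mitochondrial mRNAs 8 were lower, and none was higher at an adjusted p under 0.05, with mt-Co1 3.68-fold, mt-Nd1 6.05-fold, mt-Cytb 4.20-fold and mt-Nd6 12.4-fold lower. These mRNAs took 1.96 ± 0.317% of counts in LZ cells and 0.347 ± 0.0438% in PD cells. The 6 lists were called lower by camera, but none held with an estimated correlation. With an estimated correlation the adjusted p = 0.328 for the unfolded protein response and the dioxygenases, 0.14 for p53 targets, 0.448 for ATF4 targets, 0.278 for methyltransferases and 0.384 for mitochondrial mRNAs.

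Other lists went both ways and were not called. Nuclear-encoded oxidative phosphorylation had 42 of 64 genes higher and 15 lower, with Ndufb5 and Cox8c higher and Ndufa1 and Cycs lower. The piRNA pathway had 18 of 28 higher and 7 lower, with Ddx25 and Henmt1 higher and Btbd18 lower. G2/M genes had 19 of 34 higher and 11 lower, with the cyclin Ccnb2 higher and Ccna2, Top2a and Mad2l1 lower. S phase genes had 12 of 34 higher and 21 lower, with Chaf1a and Rfc2 higher and Orc6 and Mcm5 lower. Hypoxia-inducible factor targets had 8 of 24 higher and 14 lower, with Pfkfb4 higher and Slc2a1 and Ero1l lower. Spermatogonia markers had 6 of 17 higher and 11 lower, with Etv5, Foxo1, Sohlh2 and Crabp1 lower.

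Markers of somatic testis cells also differed in direction. Sertoli cell markers had 2 of 8 higher and 6 lower, with the protease Ctsl 217-fold lower, Amhr2 and Amh lower and Espn higher. Peritubular and stromal markers had 6 of 13 higher and 7 lower, with Fn1 38.3-fold lower, Fbln1 lower, and Postn and Col5a1 higher. Macrophage and leukocyte markers had 3 of 6 higher and 3 lower, with Aif1 at 1482 ± 152 against 0.382 ± 0.662, C1qb higher, and H2-Ab1 and Cd68 lower. Of 9 endothelial markers 6 were higher, Vwf, Cdh5, Flt1 and Tek among them. Of the 2 Leydig cell markers Scarb1 was higher and Star lower. The call of Cdh5 rested on 2 libraries, since without PD untreated A or B it fell under the filter and was not tested. Of the counts in untreated LZ cells, Sertoli markers took 0.0376 ± 0.00208% and peritubular markers 0.026 ± 0.00244%, and in untreated PD cells 0.00158 ± 0.000196% and 0.00375 ± 0.000129%.

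In all, 8579 of 16881 genes were higher and 6574 lower in PD cells at a limma adjusted p under 0.05. Camera called 13 lists, 3 higher and 10 lower, and 1 of them, the early meiotic markers, was also called with an estimated correlation. Adjusted over the list alone, counts of higher and lower members were those given, except 455 lower X-linked genes. The median of all genes was 0.49 with TMM and -0.02 with total-count scaling, and with that scaling 7477 genes were higher and 7804 lower, so which direction held more genes depends on the scaling. Stage cannot be separated from culture time, 6 days against 48 hours, or from the sort.

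**Figure D1:**
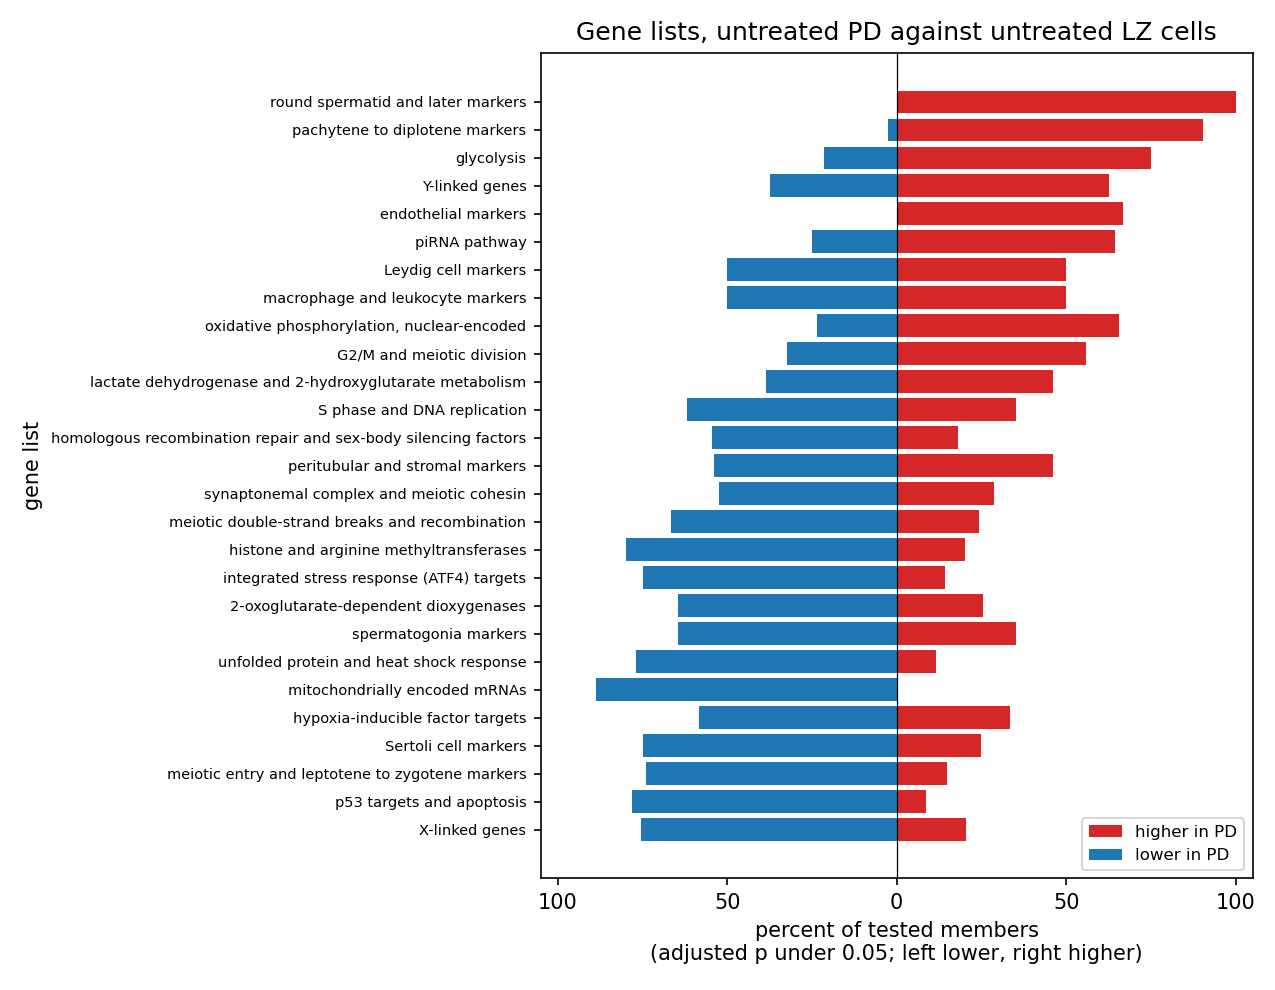
Percent of the tested members of each gene list (vertical axis) with an adjusted p under 0.05 in untreated PD against untreated LZ cells, n = 3 libraries each. Bars to the right are members higher in PD and bars to the left members lower, each from 0 to 100 percent. All 37 round spermatid markers were higher and 454 of 601 X-linked genes were lower.

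Octyl-L2HG in LZ cells asks what added L-2HG changes at the early stage. Cyp1a1, a cytochrome P450 that oxidizes aromatic compounds (chromosome 9, 57687928 to 57703824), rose 18.5-fold, from 16.1 ± 6.87 to 295 ± 18.7 (log2 fold change 4.21, SE 0.35, adjusted p = 0.000128). Ccno, a cyclin-like protein known from multiciliated cells (chromosome 13, 112987802 to 112990777), rose 4.87-fold to 189 ± 31.8. Gas2l3, a cytoskeletal linker (chromosome 10, 89408823 to 89443967), rose 3.14-fold to 472 ± 18.1. Nfe2l2, which encodes the antioxidant transcription factor NRF2 (chromosome 2, 75675513 to 75704641), rose from 628 ± 56.1 to 1172 ± 75.8 (log2 fold change 0.90, SE 0.13, adjusted p = 0.00572). Also higher were Pgap1, which remodels GPI anchors, Gnao1, a G protein subunit, Lgals8, a galectin, and Ech1, a peroxisomal and mitochondrial enzyme, at log2 fold changes of 1.08, 0.97, 0.88 and 0.74. The call of Nfe2l2 was lost without treated A (adjusted p = 0.0521). That of Pgap1 was lost without untreated A or B (0.0621 and 0.0536) or treated A, B or C (0.147, 0.0648 and 0.106). In a fit of only the LZ libraries Pgap1, Gnao1 and Ech1 were not called, nor was Ech1 with voom weights.

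Lactate dehydrogenase genes and D2hgdh did not pass the test. Ldhc had a log2 fold change of 0.16 (SE 0.33, adjusted p = 0.894), Ldha of 0.08 (SE 0.21, adjusted p = 0.923) and D2hgdh of 0.55 (SE 0.27, adjusted p = 0.419). No lower gene met the rule for naming; the 4 lower genes, named after their values were seen, were Trpd52l3, Il3ra, Fuz and 4932422M17Rik, all with means under 100. Fthl17a, an X-linked ferritin-like gene, rose by a log2 fold change of 1.29 (adjusted p = 0.0224) and was the 1 X-linked gene called. That call was lost without untreated A (0.0571) or treated A, B or C (0.125, 0.0728 and 0.0619), and in a fit of only the LZ libraries. The X-linked list was lower than other genes in camera (adjusted p = 0.000797, and adjusted p = 0.932 with an estimated correlation), at a median log2 fold change of -0.04 against 0.07 for autosomal genes. Its members with the smallest p after Fthl17a were Tsga8, 1700080O16Rik and 1700010D01Rik, at -0.89, -0.45 and -0.95 and adjusted p-values of 0.137, 0.156 and 0.165. The 13 Y-linked genes had a median of -0.18 (camera adjusted p = 0.0212, and adjusted p = 0.932 with an estimated correlation) and no called member, adjusted over the list alone or over all genes. Eif2s3y, Gm4064, Gm3376 and Gm21860 had log2 fold changes of -0.19, -0.46, -0.55 and -0.65. Over the X-linked list alone 1 member was called higher. Without untreated C the adjusted p was 0.132 for the X-linked and 0.174 for the Y-linked list, and without treated A or B it was 0.1 and 0.0912 for the Y-linked list. Neither list was called under fry or without a filter on low counts.

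Of the other 25 lists none was called by camera, and limma called no member over all genes. Without untreated C, oxidative phosphorylation (adjusted p = 0.0049) and round spermatid markers (0.0367) were called lower, the former also without treated A (0.00854) and with total-count scaling of all libraries. Adjusted over the list alone, glycolysis had 3 higher and 1 lower member, pachytene and diplotene markers 3 higher, the piRNA pathway 3 higher and 2 lower, recombination repair and sex-body factors 2 higher, ATF4 targets 1 higher and oxidative phosphorylation 1 lower. Shares of counts of the stage and somatic marker lists were close to those of untreated LZ cells, for instance 1.01 ± 0.0177% against 1.05 ± 0.0612% for early meiotic markers and 0.492 ± 0.00237% against 0.533 ± 0.0335% for pachytene and diplotene markers. In all, 36 of 13039 genes were higher and 4 lower at a limma adjusted p under 0.05, and 1322 were higher and 372 lower at an unadjusted p under 0.05. In 19.1% of genes the groups did not overlap, where chance gives 10%. Total-count scaling gave 22 higher and 8 lower genes, and a fit of only the LZ libraries 12 higher and 0 lower by limma, as voom weights gave 22 and 0. The authors' deposited table had 78 higher and 56 lower genes, of which 28 and 3 were shared with the calls here. Without 1 library the higher genes numbered 25, 59 and 20 (untreated A, B and C) and 17, 21 and 19 (treated A, B and C), and the lower ones 3, 8, 1, 2, 2 and 7 in the same order.

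Oxamate in PD cells asks what lowering 2HG, and blocking lactate dehydrogenase, changes at the later stage. Psat1, an enzyme of serine synthesis, rose from 453 ± 147 to 1219 ± 256 (log2 fold change 1.46, SE 0.22, adjusted p = 0.00229), and Slc38a2, a neutral amino acid transporter, from 243 ± 24.5 to 629 ± 167. The other large rises that met the naming rule were those of Sos2, an activator of RAS, Maz, a zinc finger transcription factor, Rbm38, an RNA-binding p53 target, Cflar, an inhibitor of death receptor signalling, Usp36, a deubiquitinase, and Tnks2, a tankyrase, with log2 fold changes of 1.24 to 1.58. The 8 largest falls that met it were those of Tpd52, Ptpn3, a tyrosine phosphatase, Plcb2, a phospholipase, Vmn2r1, Manba, a lysosomal mannosidase, Slc16a6, a monocarboxylate transporter family member, Prox2os and Rapgef4, from -2.06 to -1.21. Tpd52 fell from 183 ± 35.6 to 43.6 ± 10.2 and Slc16a6 from 417 ± 36.7 to 176 ± 6.95. Calls were lost for Usp36 without untreated C or oxamate B (adjusted p = 0.0546 and 0.0568), for Ptpn3 without untreated C or oxamate A (0.0793 and 0.0553) and for Prox2os without untreated C (0.051). Rapgef4 lost its call without any one of the 6 libraries (0.0599 to 0.124).

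ATF4 targets, the genes of the integrated stress response, were higher as a list by camera (adjusted p of 0.00223), but not with an estimated correlation (adjusted p = 0.919) or under fry (0.124). It had 6 of 26 members called, none called lower (0 also adjusted over the list alone) and a median log2 fold change of 0.46. Beside Psat1 these included Sesn2, a stress-induced sestrin, Shmt2, mitochondrial serine hydroxymethyltransferase, and Cth, which makes cysteine, at 0.71, 0.70 and 1.42. The list had 9 higher members adjusted over the list alone, and without oxamate A its camera adjusted p was 0.0535. Without untreated C the adjusted p was 0.0604 for Sesn2, 0.0664 for Shmt2 and 0.0726 for Cth, without oxamate B it was 0.0557, 0.0693 and 0.0888, and without oxamate A it was 0.0649 for Shmt2 and 0.0593 for Cth. The unfolded protein list had 5 of 24 members higher and was not called (camera adjusted p = 0.35), with Hyou1, a chaperone, rising from 6075 ± 529 to 9589 ± 429, and Sel1l, Pdia6 and Creld2 at 0.40, 0.30 and 0.45. Of 19 p53 targets and apoptosis genes 5 were higher (camera adjusted p = 0.35), with Apaf1 at 27.1 ± 2.20 against 9.65 ± 0.725 and Trp53inp1, Mdm2 and Bbc3 at 0.83, 0.36 and 1.27. Adjusted over the list alone, 6 unfolded protein genes were higher and 0 lower, and 6 p53 targets were higher and 1 lower. Most members of the ATF4, unfolded protein and p53 lists were higher in LZ cells, 21 of 28, 20 of 26 and 18 of 23. Of all 4927 tested LZ-higher genes 708 were called higher with oxamate. The lists were not compared with genes matched on the stage difference. Calls were lost for Sel1l without oxamate B (0.0602), for Pdia6 without any one library (0.0555 to 0.116), and for Creld2 without any but untreated A (0.0537 to 0.135). Mdm2 lost its call without untreated C, oxamate A or oxamate B (0.0685, 0.0657 and 0.0662). Bbc3 lost it without untreated B or C or oxamate C (0.103, 0.168 and 0.0811), and without oxamate B it was not tested. Bbc3 was also not called with voom weights, in a fit of only the PD libraries, without a filter or in the authors' table, and was not tested with total-count scaling. Trp53inp1 was not called with voom weights, and Pdia6 not with median-of-ratios or total-count scaling or in the authors' table.

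Genes of 2HG metabolism moved in part. Ldhd, the mitochondrial D-lactate dehydrogenase, fell from 70.9 ± 7.49 to 21.2 ± 2.35 (log2 fold change -1.69, SE 0.18, adjusted p = 0.000305), while Glud1 and Idh3a rose by 0.59 and 0.30. The list had 3 of 26 members higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.379). Idh3a lost its call without any one library (0.0503 to 0.128), and Glud1 without any but untreated C (0.052 to 0.119). Both lost it with voom weights, total-count scaling and a fit of only the PD libraries. Idh3a also lost it with median-of-ratios scaling, without a filter, with the block and the length and GC correction, and in the authors' table. Ldhc, Ldha and D2hgdh had log2 fold changes of 0.03, 0.09 and -0.45 with SEs of 0.33, 0.21 and 0.27 and adjusted p-values of 0.982, 0.896 and 0.386. Among 43 tested 2-oxoglutarate-dependent dioxygenases 7 were higher and 2 lower (camera adjusted p = 0.35), with Kdm6b, an H3K27 demethylase, at a log2 fold change of 0.80, Alkbh5, an RNA demethylase, at 0.57, and the lysine demethylases Kdm5a and Kdm3a at 0.39 and 0.42. Of 24 histone and arginine methyltransferases 5 were higher (camera adjusted p = 0.23), among them Setdb2, Ezh2, Suv39h1 and Ezh1 at 0.57, 0.45, 0.61 and 0.36. Adjusted over the list alone, 9 dioxygenases were higher and 4 lower, and 7 methyltransferases higher and 1 lower. Most tested members of these 2 lists were higher in LZ cells, 33 of 51 and 20 of 25. LZ-higher genes rose with oxamate in general, 708 of 4927 being called higher, and neither list was compared with genes matched on the stage difference. Kdm3a lost its call without oxamate B (0.0555), and Ezh1 without untreated C or oxamate B or C (0.0624, 0.0612 and 0.0528). Suv39h1 lost its call with voom weights.

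X-linked genes were called higher more often than autosomal ones, 41 of 308 against 893 of 14885, with 1 lower (Fisher's exact test, two-sided, p = 3.03e-06, which treats genes as independent), but the list was not called (camera adjusted p = 0.23). It was called higher without untreated A (0.00343) or oxamate B (0.00843), and adjusted over the list alone 44 were higher and 2 lower. The comparison with autosomal genes does not account for the stage difference. Of 4927 tested genes higher in LZ cells on any chromosome, 708 were called higher with oxamate, and 158 of the 308 X-linked genes were higher in LZ cells. The median change of those 158 did not pass the upper limit of autosomal lists matched on stage difference and mean expression. Hcfc1, a transcriptional coregulator, rose from 111 ± 1.29 to 207 ± 16.8, Kif4, a kinesin, 2.46-fold, Gm364 2.47-fold and 8030474K03Rik 2.14-fold. The chromosome took 0.225 ± 0.0159% of counts with oxamate and 0.227 ± 0.0243% without. Of 29 Y-linked genes limma called none, over all genes or over the list alone (camera adjusted p = 0.744).

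Peritubular and stromal markers were lower as a list by camera (adjusted p of 0.00758) and under fry (0.0445), but not with an estimated correlation (adjusted p = 0.538) or without a filter. Lum, a matrix proteoglycan, was called at -1.35 from 33.0 ± 8.88 to 12.1 ± 1.55, 1 of 9 members over all genes. Fbln1 and Cnn1 had log2 fold changes of -0.65 and -1.36 and Postn of 0.80, with adjusted p-values of 0.128, 0.135 and 0.128. Postn and Cnn1 were called with pseudocount 5, in a fit of only the PD libraries and in the authors' table, and Postn with voom weights. The list had 3 lower and 1 higher member adjusted over the list alone. It took 0.00335 ± 0.000264% of counts against 0.00375 ± 0.000129%. Endothelial, macrophage, Leydig and Sertoli cell markers had no called member over all genes by limma, with medians of -0.35, -0.25, -0.42 and 0.28, and 1 Leydig marker was lower over the list alone. Camera called none of these 4 lists, while fry called the 2 tested Leydig markers lower (adjusted p = 0.00258, against 0.122 by camera and 0.538 with an estimated correlation). Lum lost its call without any one library (0.0601 to 0.128), without a filter and with pseudocount 0.5.

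Single members were called in several meiotic and cell cycle lists. Hormad2 and Majin, of chromosome axes and telomere attachment, rose by 0.49 and 0.48 (2 of 20 synaptonemal complex genes), and Topbp1, which recruits ATR in sex-body silencing, by 0.48. Tex101, a germ cell surface protein, fell by 0.40 on the log2 scale and was the 1 called gene of 41 pachytene and diplotene markers, with 0 lower adjusted over the list alone. It was not called after a correction for transcript length and GC content, with or without the block, at -0.32. Fen1, a flap nuclease, and Ndc80, of the kinetochore, fell by 0.59 and 0.51 on the log2 scale, and Ccne1, a cyclin, rose by 0.66. Calls were lost without any one library for Majin (0.051 to 0.147) and Ccne1 (0.06 to 0.168), and without any but untreated C for Fen1 (0.0508 to 0.133). They were also lost for Hormad2 (untreated A or B, oxamate B or C, 0.0646 to 0.0787), Topbp1 (untreated A or C, oxamate B or C, 0.0623 to 0.0816), Ndc80 (untreated B or C, oxamate A or B, 0.0604 to 0.0989) and Tex101 (untreated C, oxamate B or C, 0.063 to 0.148). Fen1 and Ccne1 lost their calls with voom weights and without a filter, as Majin did without a filter. Kdm3a was also the 1 called gene of 16 hypoxia-inducible factor targets. Recombination, early meiotic, round spermatid, spermatogonia, glycolysis, oxidative phosphorylation, mitochondrial and piRNA lists had no called member by limma, over all genes or over the list alone. Round spermatid markers were called lower without oxamate A (camera adjusted p = 0.018) and oxidative phosphorylation higher without oxamate C (0.0362).

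In all, 934 of 15233 genes were higher and 252 lower with oxamate at a limma adjusted p under 0.05, 2244 and 967 at an unadjusted p under 0.05, and in 34.4% of genes the groups did not overlap, where chance gives 10%. The authors' deposited table had 1139 higher and 537 lower genes, of which 827 and 225 were shared. With total-count scaling 753 were higher and 385 lower, and with a fit of only the PD libraries 1395 and 723. Without 1 library the higher genes numbered 612, 627 and 567 (untreated A, B and C) and 712, 444 and 584 (oxamate A, B and C), and the lower ones 153, 110, 96, 140, 113 and 160 in the same order.

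**Figure D2:**
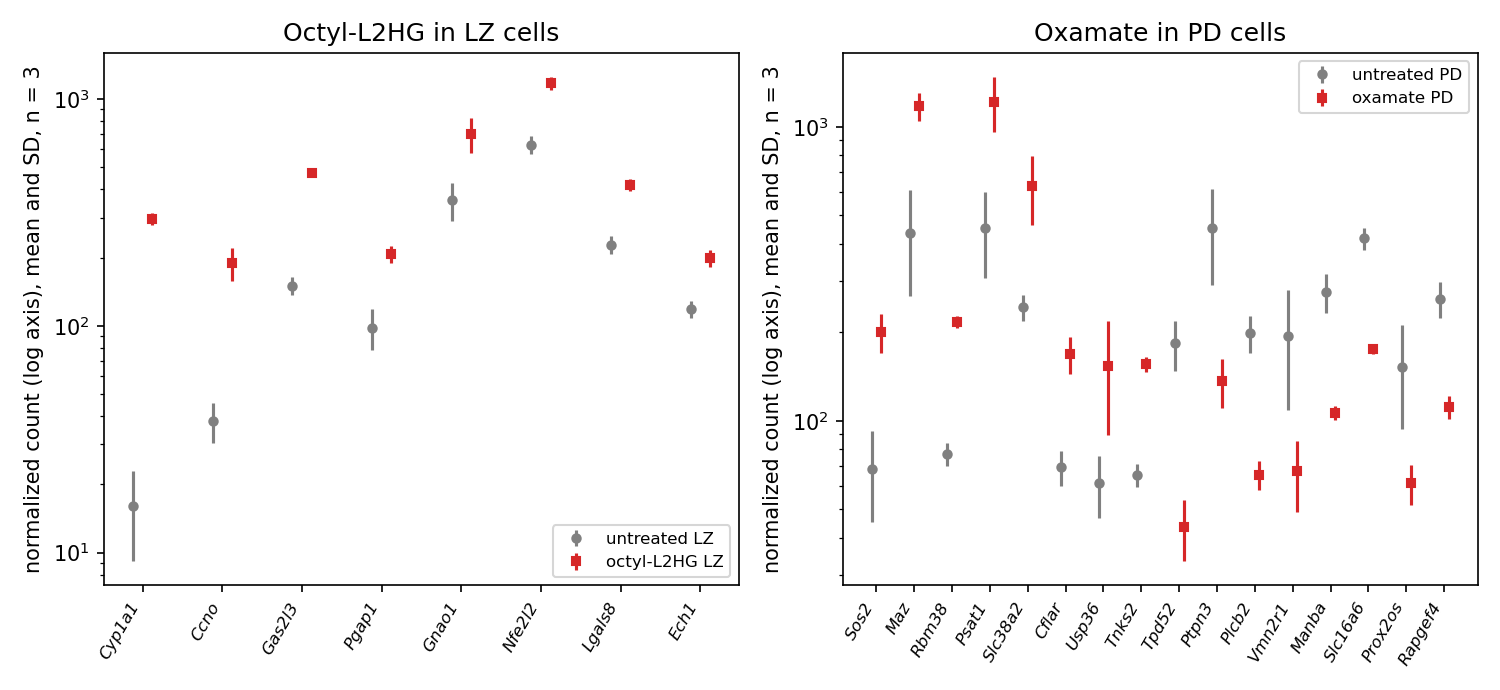
Normalized counts (log axis) of the genes with the largest called changes that met the naming rule, as group means with SD, n = 3 libraries per group. Circles are untreated and squares treated cells, for octyl-L2HG in LZ cells on the left and oxamate in PD cells on the right. Cyp1a1 stands at 295 with octyl-L2HG and 16.1 without, and Tpd52 at 43.6 with oxamate and 183 without.

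The difference between the treatment changes tests whether a gene responded unlike to octyl-L2HG in LZ and oxamate in PD cells. Ldhd, Rbm38, Apaf1 and Lgals8, already named and chosen here after their values were seen, differed. The differences, octyl-L2HG minus oxamate, were 1.94, -1.43, -1.39 and 0.87 with SEs of 0.25, 0.15, 0.20 and 0.12 and adjusted p-values of 0.0045, 0.00322, 0.00721 and 0.00721. X-linked genes were lower in this difference, 12 of 201 called lower and 0 higher (2 adjusted over the list alone, with 28 lower), at a median of -0.33 and a camera adjusted p of 5.66e-05, with an adjusted p = 0.933 with an estimated correlation. Peritubular and stromal markers were higher, with 0 of 6 called in either direction over all genes or over the list alone, a median of 0.77, a camera adjusted p of 0.00882 and an adjusted p = 0.673 with an estimated correlation. Under fry neither list was called, while the 2 tested Leydig markers were (higher, adjusted p = 0.00749, against 0.14 by camera and 0.673 with an estimated correlation), and the peritubular list was not called without a filter or with total-count scaling. In all, 58 of 11261 genes differed upward and 78 downward at a limma adjusted p under 0.05; with the code as a block the numbers were 130 and 214. Without 1 library the upward genes numbered 22 to 87 and the downward ones 10 to 138, lowest without treated LZ C and B and highest without untreated LZ B.

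Across 17011 genes the 2 treatment changes were not related in a measurable way. Pearson's r was 0.00834 and Spearman's rho 0.0184, with permutation p = 0.8 and p = 0.75 over 100 splits of the libraries, and 52.1% of genes had the same sign. Genes are not independent replicates. The 17011 genes include some near 0 in 1 stage, whose change there says little. Only 11261 genes passed the filter in both stages, and the relation was not computed over those alone, so it does not settle whether their changes were related.

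Each treatment was also compared with the stage difference, with which it shares the untreated libraries. Genes higher in LZ cells made up 708 of the 933 oxamate-higher genes tested in both, where independent lists would share 303, and 612 when the stage difference was taken from the oxamate-treated libraries. The 252 oxamate-lower genes showed no excess of PD genes, with 129 higher in PD cells where independent lists would share 142 and 92 higher in LZ cells against 81.8. With the stage difference from the oxamate-treated libraries 97 were higher in PD cells and 122 in LZ cells. The first counts leaned slightly toward LZ genes, which was not tested. The second cannot show a lean, since the low oxamate values of these genes also enter that stage difference and push them toward LZ. The numbers that independent lists would share were not computed for them. Hcfc1, Kif4, Apaf1 and Psat1 were among the genes that rose with oxamate. Median oxamate changes were 0.35 for genes with a stage difference under -6 on the log2 scale and -0.12 for genes over 6. Across genes r was -0.274 and rho -0.298, where simulated libraries with the measured stage difference and no treatment change gave -0.0422 and -0.0327 through the shared libraries. For octyl-L2HG r was 0.101 and rho 0.0403, against 0.0458 and 0.0346. Simulated groups with no stage difference either gave r of -0.507 for oxamate and 0.506 for octyl-L2HG, both larger in size than observed. Most tested genes differed between the real stages, so that setting is unlike the data. Without treated library C the octyl-L2HG r was -0.0832, so its sign rests on that library, and without treated A it was 0.182.

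**Figure D3:**
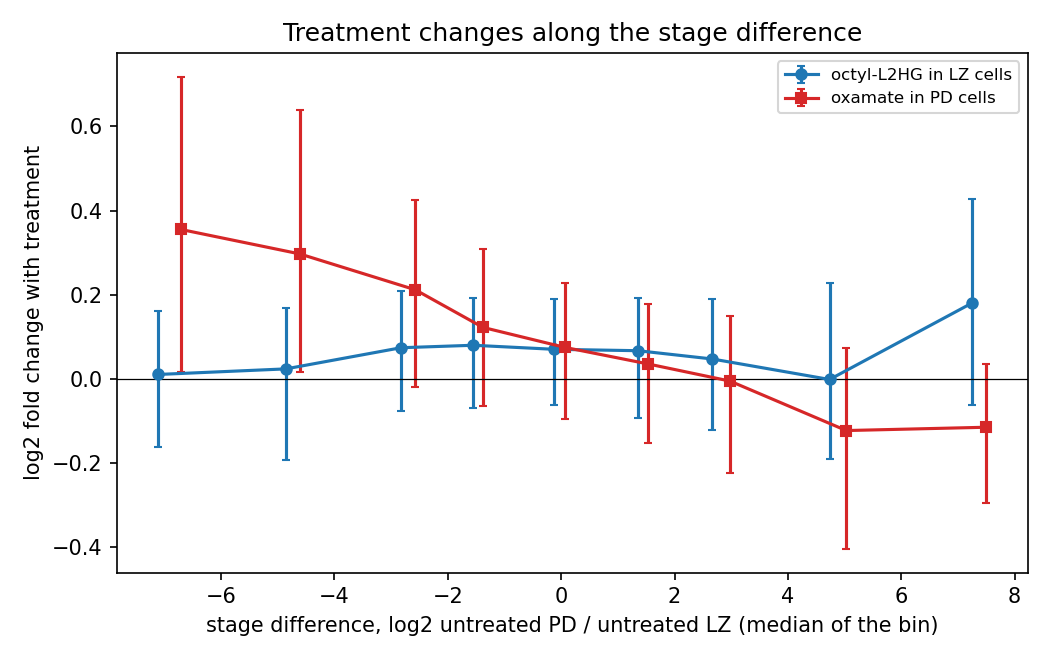
Median log2 fold change with treatment (vertical axis, bars from the 25th to the 75th percentile of genes) against the median stage difference of 9 bins of genes (horizontal axis, log2 of untreated PD over untreated LZ). Circles are octyl-L2HG in LZ cells and squares oxamate in PD cells. The oxamate medians run from 0.35 in the bin of genes lowest in PD cells to -0.12 in the bin of genes highest there.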

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

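The tests added after the results were seen are the authors' deposited comparison, limma with voom weights, the length and GC correction and the filter over 12 libraries; the planned quasi-likelihood and median-of-ratios count tests were not run, for the reason given with the processing. The counts of the stage comparison stayed within 1.5 times of those reported under every planned scaling, filter, pseudocount and block, with 8256 to 8661 genes higher and 6234 to 6503 lower without 1 library. Genes given in the report for that comparison kept their direction and call, except Cdh5 without PD untreated A or B, and the counts of the other comparisons moved more, for causes that were not tested unless fewer libraries or a stricter threshold is the construction itself. Octyl-L2HG gave 22 higher and 8 lower genes with total-count scaling, 12 and 0 with only the groups compared (fewer libraries for the spread), 13 higher at an absolute log2 fold change of at least 1, 10 lower with the filter over 12 libraries, 22 and 0 with voom and 78 and 56 in the authors' deposited comparison; without 1 library it gave 17 to 59 higher and 1 to 8 lower. Oxamate gave 385 lower genes with total-count scaling, 583 with pseudocount 5, 723 with only the groups compared, 468 with voom, 403 with the replicate block and length and GC correction and 537 in the authors' deposited comparison, 102 higher and 98 lower at an absolute log2 fold change of at least 1, and 444 to 712 higher and 96 to 160 lower without 1 library. The difference of the treatment changes gave 101 up and 198 down with median-of-ratios scaling, 127 and 261 with total-count scaling, 31 and 28 without a filter, 92 up with pseudocount 5, 130 and 214 with the replicate block, 29 and 36 at an absolute log2 fold change of at least 1, and 22 to 87 up and 10 to 138 down without 1 library. The replicate block left the other counts within 1.5 times, with 1230 higher and 309 lower for oxamate and 44 higher and 5 lower for octyl-L2HG. That block gave a code the same effect in both stages. Untreated LZ and PD libraries of the same code correlated at only 0.0333, 0.0351 and 0.104 after group means were removed. Pairing by code within a stage was not fitted gene by gene.

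Of lists, octyl-L2HG had 2 called, 0 without a filter, with an estimated correlation and under fry, 1 with the filter over 12 libraries, and 1 to 2 without 1 library. Oxamate had 2, 1 without a filter, 0 with an estimated correlation, and 2 to 3 without 1 library. The stage comparison had 13, 1 with an estimated correlation, 26 under fry, which does not compare a list with other genes, and 13 in every fit without 1 library. The difference had 2, 1 with total-count scaling, 0 with an estimated correlation, 1 under fry, and 2 to 4 without 1 library. Macrophage and leukocyte markers changed direction in the stage comparison under fry (adjusted p = 1.09e-05), where their median, 0.84, and the camera test differ in sign. The relation of the treatment changes ranged from -0.0128 to 0.0273 without 1 library, and the block cannot move it, since the design is balanced. The relation with the stage difference ranged from -0.0832 to 0.182 for octyl-L2HG, changing sign without treated library C, and from -0.296 to -0.237 for oxamate, with -0.317 at a mean normalized count of at least 100. Depth limits low genes, and 3 libraries per group limit changes under 2-fold, of which the simulation missed many.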

Other observations

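The tests of the patterns were chosen after those patterns had been seen. The outcome each would need was written before its value was computed, though values of all but the aryl hydrocarbon receptor test were then seen once under the filter over 12 libraries, before that filter was changed. The aryl hydrocarbon receptor list was written last, after Cyp1a1 and Nqo1 had been seen. The test of the share over all LZ-higher and PD-higher genes was added after the share of the 50 abundant genes had been seen, with no outcome written before. The reading of the X-linked test was loosened after its value was seen.

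Among further genes that rose with octyl-L2HG, chosen after their values were seen, was Ahrr, the repressor of the aryl hydrocarbon receptor, from 4.33 ± 3.21 to 78.6 ± 1.99 (SD, n = 3), a log2 fold change of 4.06. Nqo1, a quinone reductase, rose from 16.0 ± 2.16 to 83.0 ± 3.89, and Myo18b, an unconventional myosin, from 39.7 ± 8.52 to 135 ± 15.1. Txnrd1, a thioredoxin reductase, and Gclm, of glutathione synthesis, rose by 0.72 and 0.47 on the log2 scale. The limma adjusted p-values were 0.000342, 0.0158, 0.000128, 0.000825 and 0.0385.

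Of the genes called higher with oxamate and also tested between the stages, 708 of 933 were higher in LZ cells, while the genes that fell showed no such excess of PD genes (129 of 252). LZ RNA carried into the oxamate libraries would need a share of 4.34% (3.86 to 5.03 without 1 library, 2.89 with the stage difference from the oxamate libraries) to give the gap in median change between all LZ-higher and all PD-higher genes. The 50 most abundant LZ-specific genes gave a median of 0.172% (quartiles -0.0238 and 0.655), which argues against carry-over as the whole cause, but 36 of them rose, 11 called higher and 0 lower by limma, so a small share stays open. After a correction for transcript length and GC content, the difference in median oxamate change between LZ-higher and PD-higher genes was 0.159, from 0.184 before, and 0.145 to 0.174 without 1 library, so that bias is not the whole cause. Whether a relaxed silencing of the sex chromosomes takes part stays open. The 158 X-linked genes lower in PD cells had a median change of 0.28, at the 94.26 percentile of matched autosomal lists. By the outcome written before, a median at or below the upper limit of those lists, 0.292, counted against this cause. That limit lies within the spread of the median, 0.0542, which treats genes as independent. The X chromosome took 0.225 ± 0.0159% of counts with oxamate and 0.227 ± 0.0243% without.

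Of the 33 octyl-L2HG-higher genes also tested between the stages 26 were higher in PD and 5 in LZ cells, where independent lists would share fewer and more, and 21 and 7 with the stage difference taken from the treated libraries. All 4 octyl-L2HG-lower genes were higher in PD cells too. PD cells or RNA in treated library C could account for a rise of abundant PD-specific genes, since the median change of 50 of them was 0.237 with that library and -0.165 without it. Their levels in that library, as a share of the PD level, were uneven, with an interquartile range of 0.886 around a median of 0.673%. Much of that share was also present in the other LZ libraries. Medians were 0.506%, 0.314% and 0.385% in untreated A, B and C, and 0.35% and 0.263% in treated A and B. For these genes carry-over, a change in the cells and other differences of that library cannot be told apart with 1 library. Of these 50 genes limma called 0 higher and 0 lower. Without treated C limma still called 19 genes higher, all of them also called with it, so those 19 calls did not rest on that library. How many of the 19 were higher in PD cells was not counted. No direct biological test was made.

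Nfe2l2, Txnrd1 and Gclm, of the NRF2 pathway, rose with octyl-L2HG. A wider NRF2 response may be involved, as a list of 24 further targets was higher than other genes (camera p = 0.00247, without Nqo1 0.0121, without 1 library 0.000443 to 0.025), but p = 0.178 with an estimated correlation, and 1 member, Nqo1, was called, with 20 above and 4 below 0. A response of the aryl hydrocarbon receptor may also be involved, as a list of its targets without Cyp1a1 and Nqo1 was higher than other genes by limma's camera, with a value of 4.91e-06 for its p, unadjusted as a single list, 0.00167 with an estimated correlation and 1.67e-06 to 9.84e-05 without 1 library. It had 4 tested members, Ahrr and Cyp1b1 called at 4.06 and 1.90, and Tiparp and Slc7a5 at 0.42 and 0.13, not called. Technical explanations were not tested, and whether the ester, its octyl part or the metabolite matters cannot be known without a control compound.

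With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. The real split, 1 of the 10 in each case, gave 40 genes for octyl-L2HG against 3 at most in another, 1186 against 51 for oxamate, and 15153 against 0 by limma for the stage difference. For the difference between the treatment changes, 5 of 100 splits, the real one included, gave at least its 136 genes, a share that is not under 0.05, and the highest other gave 1582. The 4 others as large all kept the oxamate groups or their mirror, so they carry the difference between those groups, and the share is no measure of chance alone. Among the 85 that broke both groupings the highest gave 21.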
